A study of Mus musculus with 12 samples.

How the data were processed

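Gene expression was measured in newborn mouse forebrain, collected on postnatal day 0, from 4 genotypes with 3 biological replicates each. Per the labels' protocols, total RNA was isolated with Trizol, labelled with biotin and hybridised to Affymetrix Mouse Gene 1.0 ST arrays, 1 array per replicate. The values were made by RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects the background, normalizes the arrays against each other and summarises the probes of each probe set. The deposited table holds these values on a log2 scale, between 2.82 and 13.83, and the scale was taken from this range. The version of the software, the probe set library, the genome build and the annotation are not given in the sources used here. The array medians ran from 6.52 to 6.69, and no further normalization was applied. No signal of control or background probes was available, so the number of arrays and RMA's floor for dim probe sets limit the precision. The smallest median absolute difference between any pair of arrays was 0.102, so no array was a copy of another.

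The table holds 35556 probe sets. A GEO platform annotation listed 23410 of them, 21789 with 1 gene symbol and 1621 with several, and the other 12146 were not listed there and had no name here. Symbols were updated through gene identifiers to a RefSeq gene table of assembly GRCm38.p6, which held 21698 of the probe sets with 1 symbol and was used for names only, so no coordinates are given. These probe sets covered 19938 genes, of which 999 had more than 1. For each gene the probe set with the highest mean over the 12 arrays was kept. A gene was tested where that probe set lay above the 40th percentile of its array in at least 3 of the 12 arrays, which left 14195 genes. Probe sets with several genes or no name were tested separately, with the same filter.

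One linear model with a mean per genotype was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 8 residual degrees of freedom and 2.9 prior degrees of freedom. The contrasts were GBS against Control, GS against Control, GB against Control, GBS against GS, GBS against GB, and an interaction, (GBS minus GS) minus (GB minus Control). A gene was called higher or lower at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested in that contrast, two-sided, with no limit on the fold. Every adjusted p of a gene below is from this limma fit unless another is named. Errors beside a log2 change are the fit's standard errors, and errors beside a group mean are standard deviations.

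The design, the contrasts, the gene lists, the rule for naming genes and most other settings tried were set before the data were examined. The 22 gene lists were SHH pathway targets, WNT/beta-catenin targets, oncofetal and LIN28-linked genes, neural progenitor and radial glia, Notch pathway, BMP pathway, proliferation, p53 targets, pallial lineage, subpallial lineage, postmitotic neurons, cortical layer neurons, astrocytes, oligodendrocyte lineage, microglia and macrophages, endothelium and pericytes, choroid plexus and cortical hem, ependyma and motile cilia, meninges and fibroblasts, erythroid cells, midbrain and hindbrain, and immediate early and heat shock genes. Each list was tested against all other genes with limma's camera, two-sided, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 132 tests of 22 lists in 6 contrasts. The test was repeated with the correlation estimated from the arrays, and limma's fry was run beside it. Counts for a list cover its tested members only, since some members lay below the filter or had no probe set of their own. Since the tissue is a mixture, cell type lists are read as levels of marker genes.

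Genes named in the text follow this rule. Smo, Ctnnb1, Gli1, Ptch1, Hhip, Axin2, Lef1, Lin28a and Mki67 were named whatever their values. The 8 largest rises and 8 largest falls in GBS against Control, and the 5 largest of each in the other contrasts, were named among called genes whose arrays did not overlap between the groups (for the interaction, among called genes). Clone names, predicted genes and sex genes were left out of this part. For each list described, up to 4 members with the lowest adjusted p were named, with members that moved against the list. A gene named outside this rule is said to have been chosen after its values were seen.

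The other settings set in this way were no filter on dim genes, a filter at the 60th percentile, the mean of a gene's probe sets, each probe set on its own, quantile normalization of the table, centring each array on its median, limma's trend and robust settings, array weights, only the groups compared, the replicate number as a block, an adjusted p under 0.01, at least a 2-fold change, an estimated correlation between genes, and leaving out each array in turn. Added after the data were seen were leaving out 3 arrays that deviated together, and as covariates each array's median over olfactory and vomeronasal receptor genes and each array's Xist value. The 1178 receptor genes on the array, 205 of them tested, are mostly silent in brain, and their level was used as a measure of background. In these 3 settings camera called 27, 31 and 30 of the 132 list tests at the preset correlation and none with an estimated one, where the lowest adjusted p were 0.245, 0.12 and 0.0573.

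The steps were tested on simulated data built from the arrays' own means, with 200 of the 14195 genes changed and the deviations shared across genes within an array kept, over 20 draws. In the simulated GBS against Control comparison, 20.4% of changes of log2 0.5, 79.8% of log2 1 and 95.0% of log2 2 were called. The recovered shares at log2 1 were 77.1% for GS against Control and 75.6% for GB against Control. The mean number of unchanged genes called per draw was 191 for GBS against Control, 3.35 for GS against Control and 0.4 for GB against Control, and with independent noise in its place 6.8, 7.8 and 8.0. All 3 comparisons were simulated in the same way, so differences between them come from the draws and are no trait of a comparison. A simulated list of genes shifted by log2 0.5 was found in 20 of 20 draws at the preset correlation and in 6 with an estimated one, with 1.4 and 0 false lists per draw. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.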

Results

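RNA levels were measured on 12 arrays from the forebrains of newborn mice of 4 genotypes, with 3 mice each. The Cre recombinase was driven by the human GFAP promoter, which is active in radial glia, the precursor cells of the developing forebrain. GS mice carried the SmoM2 allele, a form of Smoothened that signals without a ligand and switches on the sonic hedgehog (SHH) pathway. GB mice carried a Ctnnb1 allele whose exon 3 is removed by Cre, which leaves a beta-catenin that escapes degradation and switches on WNT target genes. GBS mice carried both alleles, and their arrays hold tumor tissue, per the labels. Control mice carried both floxed alleles without Cre. The series asked what the alleles do to forebrain expression in a mouse model of embryonal tumors with multilayered rosettes, a brain tumor of early childhood.

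Arrays of a genotype resembled each other most in GBS, with correlations across genes of 0.980 to 0.989, and least in GB, with 0.894 to 0.984. The first 2 principal components held 66.7% and 20.2% of the variance. GB replicate 2 lay farthest out on the first, at 70.2, and with GS replicate 3 and Control replicate 3 it deviated from its group in a shared direction (correlation of the deviations 0.739 to 0.833). Xist, the RNA of the inactive X chromosome in females, was high in GS replicates 2 and 3 (10.83 and 10.28 on the log2 scale) and GB replicates 2 and 3 (8.655 and 10.53), and at most 5.021 in all other arrays. GBS and Control therefore matched in sex, and the other comparisons did not.

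**Figure D1:**
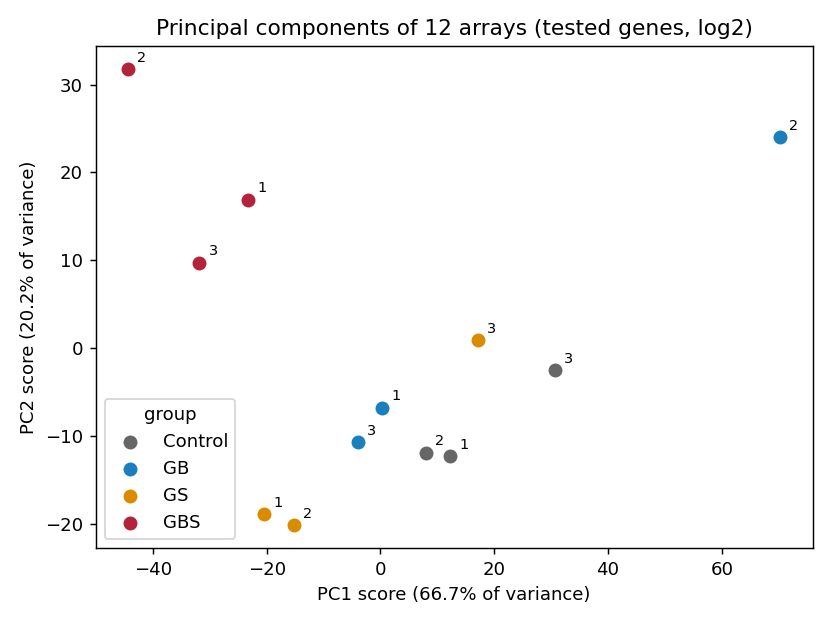
Scores of the 12 arrays on the first and second principal component of the tested genes, with 66.7% and 20.2% of the variance, coloured by genotype and numbered by replicate. GB replicate 2 lies far to the right of its group, at 70.2.

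The targeted genes come first. Smo averaged 7.11 in Control, 7.21 in GB, 7.18 in GS and 7.44 in GBS (log2, n = 3 each), and passed the test in no comparison (GBS minus Control 0.32, adjusted p = 0.0615). Without the 3 arrays that deviate together, that difference was 0.40 (adjusted p = 0.0071). Ctnnb1 averaged 8.08 ± 0.171 (SD, n = 3) in Control, 8.03 ± 0.418 (SD, n = 3) in GB, 8.68 ± 0.23 (SD, n = 3) in GS and 8.99 ± 0.173 (SD, n = 3) in GBS. It rose in GBS against Control by 0.91 ± 0.199 (adjusted p = 0.0138) and against GB by 0.96 (adjusted p = 0.0143). The first call ended without GBS replicate 2 or Control replicate 3 and with the receptor-gene level, described below, as a covariate, and the second without GBS replicate 2, with adjusted p up to 0.071 and 0.104 over all alternatives. Which parts of either transcript the probe sets cover is not given in the sources used here, so these values do not check the alleles.

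The comparison of GBS with Control asks what both alleles together do in the forebrain. Only Control mice lack Cre, so any effect of Cre itself enters each comparison with Control and cannot be separated. Of the 14195 genes, 1556 were higher and 617 lower in the tumors, 487 and 26 of them by at least 2-fold. The arrays of both groups did not overlap for 9165 genes (64.6%, where chance gives 10%). Counts of higher genes depended on single arrays: 631 without GBS replicate 2, 802, 910 and 661 without Control replicates 1, 2 and 3, and 3268 without GB replicate 2, which enters only the shared estimate of the spread. Lower genes numbered 78 without GBS replicate 2, 344 without GBS replicate 3, 371 without GS replicate 2, 2865 without GB replicate 2, and 114, 167 and 133 without Control replicates 1, 2 and 3. Each of the 1556 and 617 genes kept its direction in all of these. Leaving out a GS or GB array cannot change a direction here, and genes chosen by passing the test seldom turn, so this says little about stability. Olfactory and vomeronasal receptor genes, which read mostly background in brain, fell by a median of 0.373 on the log2 scale, with 21 of 205 past the test. That median is over the 205 tested receptor genes, while the covariate is each array's median over all 1178 receptor genes. With their level as a covariate, 787 genes were higher and 1052 lower, and 42.2% of the higher and 36.1% of the lower calls remained.

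Both pathways that the alleles switch on were higher in GBS. Of 10 SHH target genes 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a list median of 0.34. Ptch1, the SHH receptor and a direct target of the pathway, went from 7.12 ± 0.0411 (SD, n = 3) to 9.51 ± 0.207 (SD, n = 3), a rise of 5.22-fold (adjusted p = 3.87e-06). Ccnd2, a cyclin that drives entry into the cell cycle, rose by 0.95 (adjusted p = 0.00483). Hhip, a target that dampens the pathway, rose by 0.42 (adjusted p = 0.0406), but its call ended without any of 8 single arrays, with adjusted p up to 0.172 over all alternatives. Gli1, the transcription factor often used as a read-out of SHH signalling, did not pass the test (0.32, adjusted p = 0.106), except without the 3 arrays that deviate together (0.40, adjusted p = 0.00356). Camera placed the SHH list above other genes (adjusted p = 0.000718, and adjusted p = 0.108 with an estimated correlation).

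Of 17 WNT targets 11 rose and 0 fell (12 and 1 adjusted over the list alone), with a median of 0.72. Wif1, a secreted inhibitor that WNT signalling induces in feedback, rose 9.01-fold, from 6.74 ± 0.124 to 9.91 ± 0.208 (SD, n = 3; adjusted p = 2.18e-06). The feedback gene Axin2 rose by 1.78 ± 0.124 (adjusted p = 2.42e-05), Lef1, a partner of beta-catenin on DNA, by 2.27 ± 0.17 (adjusted p = 3.34e-05), and the receptor gene Tnfrsf19 by 1.503 (adjusted p = 1.7e-05). These 4 and Ptch1 kept their calls under all alternatives. Dkk1, a secreted WNT inhibitor, went against the list (-0.32, adjusted p = 0.0653, and 0.0163 over the list alone). Camera gave the WNT list an adjusted p = 1.4e-07, and adjusted p = 0.129 with an estimated correlation.

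**Figure D2:**
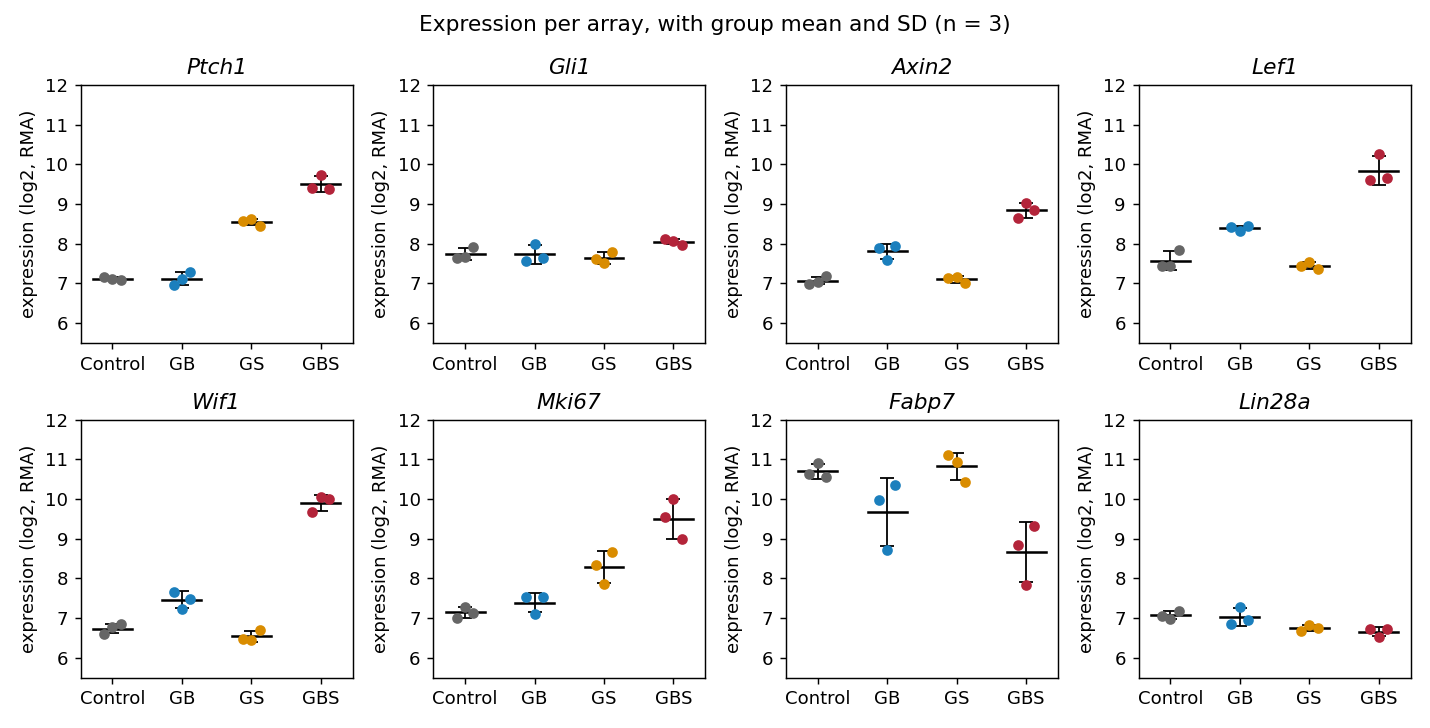
Log2 expression per array of 8 genes in the 4 genotypes, with the mean and SD of 3 arrays. Ptch1 is raised in GS and GBS, while Axin2 and Lef1 are highest in GBS, with GB means of 7.80 and 8.39 against 7.07 and 7.57 in Control.

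Genes of dividing cells rose. In the proliferation list 12 of 21 genes were higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 0.54 (camera adjusted p = 1.09e-09, and adjusted p = 0.354 with an estimated correlation). Mki67, a marker of cycling cells, rose 5.16-fold to 9.51 ± 0.504 (SD, n = 3; adjusted p = 0.000302). The mitotic checkpoint kinase gene Bub1 rose by 2.77, the spindle motor gene Kif11 by 2.50, the replication gene Mcm6 by 2.29 and the cyclin gene Ccna2 by 2.03 (adjusted p = 0.000119 to 0.000255). These 5 calls held under all alternatives.

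Progenitor genes moved apart. Of 14 genes of neural progenitors and radial glia 5 rose and 1 fell, the same over the list alone, and the list's median (-0.03) and mean (0.33) differed in sign (camera adjusted p = 0.123, and fry adjusted p = 6.54e-05 for a rise). Prom1, a surface marker of neural stem cells, rose by 1.97, Vim, the intermediate filament of radial glia, by 1.61, Pax6, a transcription factor of dorsal progenitors, by 1.48, and the glutamate transporter gene Slc1a3 by 1.246 (adjusted p = 7.19e-05 to 0.00105), under all alternatives. Against them Fabp7, a lipid-binding protein of radial glia, fell by 2.04 on the log2 scale, from 10.7 ± 0.189 to 8.67 ± 0.765 (SD, n = 3; adjusted p = 0.0121), with an adjusted p = 0.0544 without GBS replicate 2.

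Regional identity genes went both ways. The pallial list, of genes that mark the dorsal forebrain and its neurons, had 4 of 12 genes higher and 3 lower, the same over the list alone (median 0.26, camera adjusted p = 0.299). Transcription factor genes were among both: Emx2 rose by 1.88 (adjusted p = 2.94e-05), Lhx9 by 1.92 and Neurog2 by 0.92, while Neurod6 (log2 -1.85, adjusted p = 0.0487) and Tbr1 (-1.09, adjusted p = 0.0429) fell. The last 2 calls ended without any of 10 and of 8 single arrays, with adjusted p up to 0.185 and 0.176 over all alternatives. Of 16 subpallial genes, which mark the ventral forebrain and its interneurons, 0 rose and 5 fell (0 and 9 adjusted over the list alone; median -0.33; camera adjusted p = 0.000876, and adjusted p = 0.400 with an estimated correlation). The 205 tested receptor genes fell as far, though the array medians over all 1178 fell less. With those array medians as a covariate 2 subpallial genes fell (median -0.20, camera adjusted p = 0.00745, and adjusted p = 0.473 with an estimated correlation). Among the 5 were the interneuron regulator Dlx6 (-0.84, adjusted p = 0.0222) and the glial and motor lineage factors Olig1 and Olig2 (-0.44 and -0.46). Without GBS replicate 2 or Control replicate 1 none of these 3 passed, Dlx6 also failed without GBS replicate 3 or Control replicate 2, and the Olig genes without Control replicate 3, with adjusted p up to 0.110 over all alternatives.

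Neuronal genes were lower in part. In the postmitotic neuron list 0 of 15 genes rose and 3 fell (0 and 4 adjusted over the list alone), with a median of -0.56 that camera did not place apart (adjusted p = 0.0688). Without the 3 deviating arrays 1 rose and 11 fell, and camera placed the list lower (median -0.66, adjusted p = 0.00355). With the receptor genes as a covariate 0 rose in limma and 13 fell (median -1.5, adjusted p = 9.15e-12). The list had adjusted p = 0.816 with an estimated correlation on all arrays, and 0.684 and 0.32 in these last 2 settings. Receptor-gene levels did not overlap between GBS (4.844 to 4.922) and Control (5.122 to 5.231). The list's fall with that covariate is thus extrapolated from differences within groups, and its size is uncertain. The growth cone gene Gap43 fell by 1.48 on the log2 scale (adjusted p = 0.0282) and the tau gene Mapt by 0.56 (adjusted p = 0.0304). Both calls ended without GBS replicate 2 or any single Control array, with adjusted p up to 0.109 and 0.136 over all alternatives. Of 11 cortical layer genes 1 rose and 4 fell (1 and 8 adjusted over the list alone), among them Reln, a secreted guide of cortical layering, at -0.85 (adjusted p = 0.0163, up to 0.0723 without GBS replicate 2 or Control replicate 1). Cux1, a factor of upper layers, moved the other way (0.42, adjusted p = 0.0464), but its call ended without any of 8 single arrays (adjusted p up to 0.404). The list's median was -0.40 (camera adjusted p = 0.0223, and adjusted p = 0.524 with an estimated correlation), and its call ended without Control replicate 2.

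Genes linked to LIN28, an RNA-binding protein of embryonic cells that marks multilayered-rosette tumors in patients, did not rise together. Of 11 oncofetal genes 1 rose and 2 fell, the same over the list alone (median -0.22, camera adjusted p = 0.259). Other members of the list were not tested: Lin28b lay below the filter, and Hmga1, Igf2bp2 and H19 had no probe set of their own. Lin28a itself was 7.07 ± 0.102 in Control and 6.66 ± 0.125 (SD, n = 3) in GBS, lower by log2 -0.41 (adjusted p = 0.0433). That call ended when arrays were centred on their medians, with the receptor genes as a covariate and without any of 9 single arrays, with adjusted p up to 0.357 over all alternatives, so no change of Lin28a is established. Igf2bp3, an embryonic RNA-binding protein, rose by 0.53 (adjusted p = 0.0268, up to 0.209 over the alternatives, past the test no longer without GBS replicate 2, GBS replicate 3 or any single Control array). Crabp1, which binds retinoic acid, fell by 1.06 (adjusted p = 0.00244) under all alternatives.

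The other lists did not stand apart from other genes in this comparison. Among pathways, 0 of 8 Notch genes were called by limma (median -0.09, camera adjusted p = 0.627), 3 of 11 BMP genes rose (3 over the list alone; median -0.10, mean 0.17, adjusted p = 0.704), led by Bmp4 at 1.66, and 2 of 6 p53 targets rose (median 0.37, adjusted p = 0.423), led by Trp53inp1 at 0.89. Of 9 immediate early and heat shock genes 2 rose (median -0.02, adjusted p = 0.779), led by Hsph1 at 1.19. In the choroid plexus and cortical hem list 2 of 10 genes rose and 1 fell (2 and 4 adjusted over the list alone; median -0.34, mean 0.06, adjusted p = 0.609). Its rises, Clic6 by 2.38 and Sostdc1 by 2.13, held under all alternatives. Of 7 astrocyte genes 2 rose and 1 fell (median -0.17, mean 0.11, adjusted p = 0.959), and of 6 meningeal genes 1 rose, Dcn (median -0.07, mean 0.54, adjusted p = 0.946).

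Limma called 0 genes in the lists for the oligodendrocyte lineage (6 genes, 0 higher and 4 lower adjusted over the list alone, median -0.34), microglia (8 genes, -0.27), endothelium (9 genes, -0.10), ependyma (4 genes, -0.22), midbrain and hindbrain (6 genes, -0.31) and erythroid cells (2 genes, 0.04, with 1 higher over the list alone). Camera adjusted p were 0.0711, 0.113, 0.802, 0.541, 0.164 and 0.851. The median of the 205 tested receptor genes, -0.37, is as low as the lowest of these. Over all 1178 receptor genes the array medians were 4.922, 4.844 and 4.884 in GBS and 5.17, 5.122 and 5.231 in Control, a smaller fall on average. The comparison with background thus depends on which receptor genes are counted.

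By size, the largest rises in GBS went to genes outside the lists as well. Cyp1b1, an oxidising enzyme of the cytochrome family, rose 16.2-fold, from 6.67 ± 0.206 to 10.69 ± 0.22 (SD, n = 3; adjusted p = 1.54e-05). Dcn, a proteoglycan of connective tissue, rose 13.9-fold, the muscle filament gene Mybpc1 11.99-fold, the adhesion receptor gene Adgrv1 10.03-fold, the matrix protease gene Adamts19 9.19-fold and the vesicle trafficking gene Stxbp4 7.55-fold (adjusted p = 7.41e-06 to 0.00663), under all alternatives. Hmcn1, a matrix protein gene, rose 7.85-fold (adjusted p = 0.0144), with a call that ended without GBS replicate 2, Control replicate 1 or Control replicate 3 (adjusted p up to 0.105). Among the largest falls the membrane protein gene Luzp2 (log2 -1.46, adjusted p = 0.00725) held under all alternatives. Besides Fabp7, Neurod6 and Gap43 they were the calcium sensor gene Vsnl1 (-2.09, adjusted p = 0.0409), the adhesion gene Cdh12 (-1.45, adjusted p = 0.0342) and the microRNA genes Mir680-1 and Mir680-2 (-1.59 and -1.51). Each of the last 4 lost its call without GBS replicate 1, GBS replicate 2, GS replicate 2, Control replicate 2 or Control replicate 3, and without others, with adjusted p up to 0.182, 0.158, 0.583 and 0.618 over all alternatives.

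**Figure D3:**
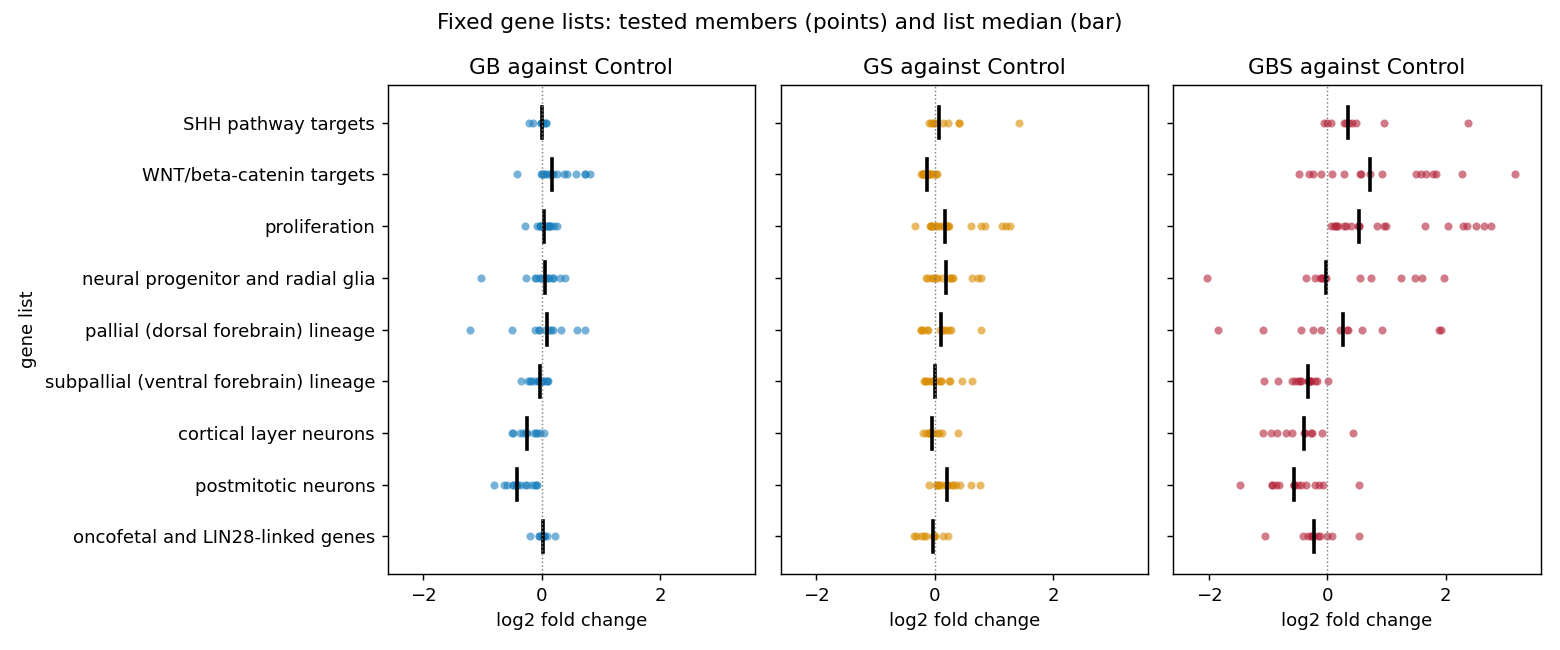
Log2 changes of the measured members of 9 gene lists in GB, GS and GBS against Control, with a point per gene and the list medians. The proliferation list has a median of 0.54 in GBS, 0.18 in GS and 0.03 in GB.

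GS against Control asks what SmoM2 does alone, together with any effect of Cre. Limma called 3 genes higher and 0 lower, with 508 higher and 331 lower at an unadjusted p under 0.05. The arrays did not overlap for 2488 genes (17.5%, where chance gives 10%). Ptch1 rose 2.69-fold to 8.55 ± 0.0835 (SD, n = 3; adjusted p = 0.00164), under all alternatives. Prm1, which encodes a protamine that packs sperm DNA, rose 4.25-fold (adjusted p = 0.00437), also under all alternatives. Its mean was also higher in GB and GBS (8.57 and 8.49) than in Control (7.31), so this rise cannot be ascribed to SmoM2 alone. The third was the predicted gene Gm10561, chosen after its values were seen (log2 1.71, adjusted p = 0.0142), which rose in GBS too (2.14, adjusted p = 0.000117). Its call in GS ended without GS replicate 1, GS replicate 3 or any single Control array (adjusted p up to 0.253). Of simulated changes of log2 1 in this comparison, 77.1% were called. That share does not carry over to the real comparison, since an adjusted p depends on how many genes change, which the simulation set. In the real data Mki67 lay 1.15 above Control with an unadjusted p = 0.000919 in limma, yet its adjusted p was 0.645. The low count of calls therefore does not show that few genes changed by log2 1.

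The SHH target Hhip (0.42), Mki67 (1.15) and Ctnnb1 (0.60) had values above Control in GS that did not pass (adjusted p = 0.645 each). Gli1 (-0.10), Axin2 (0.03), Lef1 (-0.13), Lin28a (-0.32) and Smo (0.07) did not pass either. By list, camera placed 3 above other genes. SHH targets had 1 of 10 genes higher (2 adjusted over the list alone; median 0.07, adjusted p = 0.0124, and adjusted p = 0.170 with an estimated correlation). Progenitor genes had 0 called over all genes by limma and 3 over the list alone, Slc1a3 (0.78), Vim (0.73) and Sox2 (0.63), with a median of 0.19 (adjusted p = 0.0128, and adjusted p = 0.160 with an estimated correlation). Proliferation genes had 0 over all genes and 5 over the list alone, among them Top2a (1.27) and Kif11 (1.21), with a median of 0.18 (adjusted p = 0.00137, and adjusted p = 0.667 with an estimated correlation).

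These camera calls depended on few arrays. Without GS replicate 3 none of the 3 passed, and without GB replicate 2 the SHH list did not (adjusted p up to 0.292 for the SHH and progenitor lists and 0.667 for the proliferation list over all alternatives). WNT targets had a median of -0.13 (adjusted p = 0.0560) and postmitotic neurons one of 0.21 (adjusted p = 0.0813). Without the 3 arrays that deviated together, 1400 genes were higher and 314 lower in GS, and Mki67 (0.96, adjusted p = 0.0405), Hhip (0.45, adjusted p = 0.0336) and Ctnnb1 (0.63, adjusted p = 0.0145) passed. In this setting none of the 3 lists passed (adjusted p = 0.27, 0.211 and 0.407 for the SHH, progenitor and proliferation lists), and the postmitotic neuron list lay higher, with 3 genes called (median 0.34, adjusted p = 0.00396, and adjusted p = 0.684 with an estimated correlation). With array weights 4203 were higher and 4084 lower.

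GB against Control asks what stabilised beta-catenin does alone, together with any effect of Cre. Limma called 0 genes, with 129 higher and 27 lower at an unadjusted p under 0.05, and arrays did not overlap for 582 genes (4.1%, where chance gives 10%). Axin2 was above Control by 0.73 ± 0.124, Lef1 by 0.82 ± 0.17 and Wif1 by 0.73, without passing (adjusted p = 0.494, 0.909 and 0.661). As a group WNT targets were higher in GB: camera placed the list above other genes (median 0.17, adjusted p = 1.58e-12, and adjusted p = 0.0738 with an estimated correlation), and 6 of 17 rose adjusted over the list alone. SHH genes did not move with them, with Ptch1 at -0.00, Gli1 at -0.01, Hhip at 0.07 and a list median of -0.000834 (camera adjusted p = 0.820). Ctnnb1 (-0.05), Mki67 (0.25), Smo (0.10) and Lin28a (-0.04) did not pass, and proliferation genes had a median of 0.03 (camera adjusted p = 0.335).

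The count for GB rose to 1 higher gene without GBS replicate 1, 2 without GBS replicate 2 and 7 without GB replicate 2. Without the 3 deviating arrays 25 were higher and 1 lower, among them Axin2 (0.90, adjusted p = 0.0162), Wif1 (0.89, adjusted p = 0.0247), Adamts19 (adjusted p = 0.000471) and Cyp1b1 (1.66, adjusted p = 0.00769), though not Lef1 (0.99, adjusted p = 0.0825). In camera, postmitotic neuron genes (median -0.42, adjusted p = 3.5e-06, and adjusted p = 0.636 with an estimated correlation) and cortical layer genes (-0.25, adjusted p = 3.07e-05, and adjusted p = 0.181 with an estimated correlation) lay lower in GB, with 0 single genes called by limma. Both calls ended without GB replicate 2, with medians of 0.05 (adjusted p = 0.706) and -0.13 (adjusted p = 0.219). Without all 3 deviating arrays the first median was -0.08 (adjusted p = 0.766), while the second list passed (-0.17, adjusted p = 0.0405, and adjusted p = 0.632 with an estimated correlation). A rise of the meningeal list (0.11, adjusted p = 0.00746, and adjusted p = 0.160 with an estimated correlation) ended without GB replicate 2, GB replicate 3 or Control replicate 1 (adjusted p up to 0.247).

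GBS against GS asks what the beta-catenin allele adds to SmoM2. It gave 505 higher and 215 lower genes, and arrays did not overlap for 4100 (28.9%, where chance gives 10%). With the receptor genes as a covariate 849 were higher and 1265 lower, and without the 3 deviating arrays 1164 and 1245, so the balance of directions turned. Higher genes numbered 268 without GBS replicate 2, 306 and 247 without GS replicates 1 and 2, and 1100 without GB replicate 2. Lower genes numbered 123 and 47 without GBS replicates 1 and 2, 51, 45 and 331 without GS replicates 1, 2 and 3, 580 without GB replicate 2, and 124, 123 and 129 without Control replicates 1, 2 and 3. With the Xist value as a covariate 124 and 17 were left, with all GBS arrays and only GS replicate 1 of the GS arrays low in Xist. All 505 and 215 genes then kept their sign, with medians of 0.82 against 0.87 and -0.61 against -0.56.

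WNT targets rose in 11 of 17 genes and fell in 0 (12 and 0 adjusted over the list alone), with a median of 0.82 (camera adjusted p = 4.19e-15, and adjusted p = 0.0602 with an estimated correlation). Lef1 rose by 2.39, Axin2 by 1.74, Wif1 by 3.37 and Tnfrsf19 by 1.60 (adjusted p of the first 2 = 2.99e-05). SHH targets rose beyond GS in 3 of 10 genes (6 adjusted over the list alone; median 0.35, adjusted p = 0.00240, and adjusted p = 0.129 with an estimated correlation), with Ptch1 1.94-fold above GS (adjusted p = 0.00119). All of these genes kept their calls at an adjusted p under 0.05 in every alternative. Gli1 (0.41), Hhip (0.01), Ctnnb1 (0.32), Smo (0.26) and Lin28a (-0.09) did not pass. The largest rises were Cyp1b1 (13.4-fold), Mybpc1 (log2 3.74), Dcn (3.41), Wif1 and Adamts19 (3.33), all kept under every alternative.

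Proliferation genes rose in 8 of 21 and fell in 0 (12 and 0 adjusted over the list alone; median 0.50, camera adjusted p = 3.08e-12, and adjusted p = 0.261 with an estimated correlation), with Mcm6 up by 2.05 and Bub1 by 1.92 under all alternatives. Mki67 rose by 1.22 (adjusted p = 0.0202), but not past the test without GBS replicate 1 or 2 or GS replicate 1 or 2 (adjusted p up to 0.174), nor after quantile normalization or with the Xist covariate. Emx2 rose by 2.01 (adjusted p = 2.74e-05) and Prom1 by 1.71 (adjusted p = 0.000265), under all alternatives. With the Xist covariate 9 WNT targets, 1 SHH target and 2 proliferation genes rose, with list medians of 0.93, 0.35 and 0.50. The pallial list had 3 higher and 0 lower (4 and 3 over the list alone) and the progenitor list 3 higher and 1 lower (4 and 2 over the list alone).

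Some ventral and neuronal genes were lower in GBS than in GS, though most members of each list did not pass. Subpallial genes fell in 4 of 16 (7 adjusted over the list alone; median -0.35, camera adjusted p = 1.28e-06, and adjusted p = 0.199 with an estimated correlation), led by Dlx6 at -1.47 (adjusted p = 0.00234), which kept its call under all alternatives, and Dlx1, which averaged 8.13 in GS and 7.13 in GBS (adjusted p = 0.00599) and lost its call with the Xist covariate alone (0.0878). Postmitotic neuron genes fell in 3 of 15 (5 adjusted over the list alone; median -0.77, adjusted p = 3.72e-05, and adjusted p = 0.667 with an estimated correlation) and cortical layer genes in 2 of 11 (1 higher and 6 lower over the list alone; median -0.45, adjusted p = 0.00118, and adjusted p = 0.319 with an estimated correlation). With the Xist covariate 1, 0 and 0 genes of these 3 lists fell in limma, with medians of -0.29, -0.83 and -0.51. Camera then gave adjusted p = 9.16e-06, 1.44e-07 and 0.000371, and adjusted p = 0.326, 0.502 and 0.353 with an estimated correlation. The neurofilament gene Nefm (-1.44, adjusted p = 0.0138) did not pass without GBS replicate 2, GS replicate 1 or GS replicate 2 (adjusted p up to 0.0712). Among the largest falls the nervous system gene Scrg1 (-1.74, adjusted p = 0.00291) kept its call under all alternatives. Fabp7 (-2.16, adjusted p = 0.0158), the axon growth gene Shtn1 (-1.89, adjusted p = 0.0222) and Luzp2 (-1.54, adjusted p = 0.00991) each lost theirs without GBS replicate 2 or GS replicate 2, and the first 2 also without GS replicate 1 (adjusted p up to 0.113). Cdh12 (-1.55, adjusted p = 0.0486) lost its call without any of 9 single arrays (adjusted p up to 0.232).

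GBS against GB asks what SmoM2 adds to the beta-catenin allele. It gave 1363 higher and 443 lower genes, 463 and 4 by at least 2-fold, and arrays did not overlap for 6797 (47.9%, where chance gives 10%). The median of all genes moved by log2 -0.11, and relative to it, with arrays centred on their medians, 1320 genes were higher and 256 lower. The 205 tested receptor genes fell by a median of 0.339 on the log2 scale, with 17 past the test. With the array medians over all 1178 receptor genes as a covariate, 520 genes were higher and 532 lower. Higher genes numbered 396 and 816 without GBS replicates 2 and 3, and 2199 without GB replicate 3. Lower genes numbered 242, 25 and 162 without GBS replicates 1, 2 and 3, 241 and 168 without GS replicates 1 and 2, 291, 183 and 1045 without GB replicates 1, 2 and 3, and 163, 170 and 197 without Control replicates 1, 2 and 3. With a fit to these 2 groups alone 77 were higher and 0 lower in limma, with 2346 and 1330 at an unadjusted p under 0.05, and with the Xist value as a covariate 246 and 16.

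SHH targets rose in 4 of 10 genes (7 adjusted over the list alone; median 0.34, camera adjusted p = 0.000446, and adjusted p = 0.108 with an estimated correlation), with Ptch1 5.22-fold higher (adjusted p = 7.68e-06). WNT targets rose beyond GB in 9 of 17 (12 higher and 1 lower adjusted over the list alone; median 0.47, adjusted p = 3.5e-06, and adjusted p = 0.167 with an estimated correlation). Wif1 rose by 2.45 and Lef1 by 1.44, under all alternatives, and Axin2 by 1.04 (adjusted p = 0.000956), with an adjusted p = 0.0504 in the fit to these 2 groups alone. Proliferation genes rose in 11 of 21 and fell in 0 (12 and 0 adjusted over the list alone; median 0.57, adjusted p = 5.51e-09, and adjusted p = 0.371 with an estimated correlation), with Bub1 up by 2.64, the DNA-untangling enzyme gene Top2a by 2.60 and Mki67 by 2.12 (adjusted p = 0.00103). With the Xist covariate 2 SHH targets, 7 WNT targets and 6 proliferation genes rose, with list medians of 0.35, 0.56 and 0.53. Gli1 (0.32), Hhip (0.36), Smo (0.23) and Lin28a (-0.37) did not pass.

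The largest rises were Adgrv1 (6.75-fold, adjusted p = 6.39e-05), Cyp1b1 (log2 2.69), Bub1, the kinase gene Tec (2.60, adjusted p = 4.41e-05) and Top2a, under all alternatives. Progenitor genes had 5 higher and 0 lower (6 and 1 over the list alone). Subpallial genes fell in 3 of 16 (7 adjusted over the list alone; median -0.34, camera adjusted p = 0.00377, and adjusted p = 0.524 with an estimated correlation), as far as the tested receptor genes. With the receptor-gene level as a covariate 0 were called by limma (median -0.20, camera adjusted p = 0.00677), and 0 with the Xist covariate (-0.28, adjusted p = 0.00734), with adjusted p = 0.473 and 0.502 with an estimated correlation. In the microglia list 2 of 8 genes fell, and 4 adjusted over the list alone (median -0.34, adjusted p = 0.0326, and adjusted p = 0.671 with an estimated correlation), as far as the tested receptor genes. The microglia list did not pass with the receptor genes as a covariate or without GBS replicate 1 or GB replicate 2. Postmitotic neuron genes had 0 calls in limma and a median of -0.12 (camera adjusted p = 0.605). Camera placed them lower without GB replicate 2 (-0.60, adjusted p = 0.0011). With all 3 deviating arrays left out 8 of 15 fell (median -0.60, adjusted p = 0.000333), and 8 with the receptor genes as a covariate (median -0.96, adjusted p = 1.82e-09). The list had adjusted p = 0.885 with an estimated correlation on all arrays, and 0.632 and 0.38 in these last 2 settings. Receptor-gene levels of GBS and GB did not overlap either, so the fall with that covariate is again extrapolated from differences within groups. The largest falls were Mir680-1 (-1.67), Mir680-2 (-1.53), the small nucleolar RNA gene Snord49b (-1.05), the channel subunit gene Cacng3 (-1.03, adjusted p = 0.0151) and Luzp2 (-0.99). None passed without GBS replicate 2, and all but Cacng3 lost their calls without several other arrays too (adjusted p up to 0.106 for Cacng3 and 0.515 for the others).

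The interaction asks whether GBS differs from the sum of the changes in GS and GB. It passed for 46 genes above that sum and 1 below it, of 14195. The balance of directions depended on the setting. Without the 3 deviating arrays 120 lay above and 293 below, with array weights 493 and 665, and with the receptor genes as a covariate 147 and 106. WNT targets lay above the sum in 6 of 17 genes and below it in 0 (11 and 0 adjusted over the list alone; median 0.67, camera adjusted p = 4.19e-15, and adjusted p = 0.0602 with an estimated correlation). Wif1 exceeded it by 2.64 ± 0.197 (adjusted p = 0.000576), Lef1 by 1.57 ± 0.241 (adjusted p = 0.0261), Axin2 by 1.01 ± 0.175 (adjusted p = 0.0421), and Ptch1 of the SHH list by 0.96 ± 0.167 (adjusted p = 0.0424). The largest were Tec (2.71 ± 0.242), Wif1, Cyp1b1 (2.41 ± 0.365), the caveolae gene Cavin2 (2.33 ± 0.277) and Adamts19 (2.26 ± 0.348). Prm1 lay below the sum (-2.17 ± 0.288, adjusted p = 0.0112), as it was at 8.57 ± 0.124, 9.40 ± 0.264 and 8.49 ± 0.452 (SD, n = 3) in GB, GS and GBS against 7.31 ± 0.11 (SD, n = 3) in Control. Only Control mice lack Cre, so an effect of Cre alone would enter the interaction with a negative sign, which this design cannot separate. Mki67 (0.97, adjusted p = 0.489), Gli1 (0.42), Ctnnb1 (0.37), Smo (0.16), Hhip (-0.06) and Lin28a (-0.05) did not pass.

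Camera also placed SHH targets (median 0.33, adjusted p = 0.000928, and adjusted p = 0.108 with an estimated correlation) and proliferation genes (0.52, adjusted p = 2.89e-11, and adjusted p = 0.294 with an estimated correlation) above the sum. Subpallial genes lay below it (-0.29, adjusted p = 1.08e-05, and adjusted p = 0.261 with an estimated correlation), as did postmitotic neurons (-0.22, adjusted p = 0.0335) and microglia (-0.21, adjusted p = 0.0264), which had adjusted p = 0.768 and 0.667 with an estimated correlation. The neuron list did not pass without any of 7 single arrays. It passed at -0.92 (adjusted p = 1.25e-11) without the 3 deviating arrays, -0.69 (adjusted p = 1.81e-07) with the receptor genes as a covariate and -0.60 (adjusted p = 9.8e-05) with Xist, with adjusted p = 0.62, 0.422 and 0.645 with an estimated correlation. The microglia list passed in none of these 3 settings (adjusted p = 0.543, 0.159 and 0.226), nor without GS replicate 3, GB replicate 2 or Control replicate 2.

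The number of interaction calls depended on single arrays, more than the differences did. Leaving out each array in turn kept the sign of all 46, as is likely for genes chosen by passing the test, with medians of 1.26 to 1.48 against 1.35. The 46 calls became 27 and 26 without GBS replicates 2 and 3, 18, 14 and 23 without GS replicates 1, 2 and 3, 22 without GB replicate 1, and 15, 18 and 16 without Control replicates 1, 2 and 3, while the 1 below the sum became 4 without GS replicate 3. With the Xist value as a covariate 0 genes passed in limma, with 244 above and 208 below the sum at an unadjusted p under 0.05. Wif1 then had an adjusted p = 0.0659, and all 46 kept their sign. Wif1, Tec and Cavin2 kept their calls under every other alternative. Ptch1, Axin2, Lef1, Cyp1b1 and Adamts19 each lost theirs without GS replicate 1 or 2 or any single Control array, and without others (adjusted p up to 0.484, 0.899, 0.568, 0.568 and 0.673).

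Fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, called 31 of the 132 list tests, 20 of them also called by camera at the preset correlation. It called 51 when changes in either direction counted. Fry called 3 lists higher in GBS than in Control, GS and GB that camera did not: progenitors (adjusted p = 6.54e-05, 0.00571 and 0.000234), p53 targets (0.000608, 0.00187 and 0.000234) and the pallial list (0.00293, 0.00713 and 0.0406). It also called the oligodendrocyte list lower in GBS than in GB (0.0405) and p53 targets above the sum in the interaction (0.00665). Camera calls that fry did not share were the proliferation list in GS (0.341) and the interaction (0.0551), and postmitotic neurons in GB (0.533), in GBS against GS (0.164) and in the interaction (0.601). The others were the cortical layer (0.237) and meningeal (0.111) lists in GB and microglia in GBS against GB (0.0582) and in the interaction (0.341).

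GBS stood above each of the other 3 groups for 455 genes and below each for 98. These comparisons share the GBS arrays, so some overlap is given by the design. In 20 simulated draws of unchanged groups that share arrays in the same way, limma gave at most 0 and 0 such genes. Only 1 of these draws had any call in GBS against Control. An overlap was thus nearly ruled out beforehand, and the draws cannot say what the shared arrays contribute. The changes in GS and GB against the shared Control arrays lay within the range of unchanged groups: their correlation across genes, which are not independent replicates, was -0.112, where simulated unchanged groups gave a median of 0.641 (95% of 100 draws between -0.512 and 0.962). The covariance was -0.00389 against a simulated 0.0149 (-0.0161 to 0.135), and 46.9% of genes had the same sign against a simulated 71.5% (32.8 to 93.1). As limma called 0 genes in GB, no calls could be shared. Without GBS replicate 2 there was 1 shared call, and without the 3 deviating arrays 10.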

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

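The tests of the 3 weighed patterns were chosen after the results were seen, except the test of signal over background on unnamed probe sets, whose outcome was stated before its result, and the counts over other splits of the samples.

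A test of the difference itself called genes whose change with the Ctnnb1 allele differed between mice with and without SmoM2. Of 14 named interaction calls 0 were kept under all alternatives. GBS arrays hold tumor tissue, per the labels, so differences in the make-up of the tissue enter this difference too. The difference passed for 46 genes in the direction of more expression with SmoM2 and for 1, Prm1, in the other. Without the 3 deviating arrays 120 and 293 passed. Only Control mice lack Cre, so an effect of Cre alone enters this difference with a negative sign. The design cannot separate it, and Prm1 was higher in all Cre-carrying arrays. It was log2 2.71 for Tec, 2.64 for Wif1, 2.41 for Cyp1b1, 2.33 for Cavin2, 2.26 for Adamts19, 1.57 for Lef1, 1.01 for Axin2, 0.957 for Ptch1 and -2.17 for Prm1. Of 100 splits of the 12 arrays into groups of 3, 1 gave as many calls as the real 47, the real split itself. The highest of the others gave 42. These splits exchange all genotypes at once, so they ask whether any genotype differs. They cannot exclude chance for the interaction itself, since the other differences of GBS stay in the data. The pups' sex was unbalanced, since GS and GB hold 2 arrays each with high Xist and GBS and Control hold none, and with Xist as a covariate limma called 0 genes, with 244 higher and 208 lower at an unadjusted p under 0.05, against 687 and 471 without it. The interaction and sex can therefore only in part be separated in this design. The differences kept their size, with a median over the 46 genes of 1.37 against 1.35, while the standard error was larger for all 46, with a median of 0.284 against 0.195.

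Probe sets with no gene name in the annotation, which enter none of the comparisons above, also differed between GBS and Control: of 6469 tested, 357 were higher and 178 lower. Probe sets assigned to several genes were higher in 146 and lower in 35 of 1222 cases. Unnamed probe sets were higher in 53 and lower in 122 cases in GBS against GS, and in 284 and 173 in GBS against GB. In GS and GB against Control and in the interaction limma called 0 of them, with 279 and 197, 72 and 37, and 166 and 262 at an unadjusted p under 0.05.

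GB replicate 2, GS replicate 3 and Control replicate 3 deviated together from their groups (scores on the shared component 0.697, 0.356 and 0.198, with 76.6% of the variance within groups). Sex as the shared cause was argued against, since Xist was low in Control replicate 3 (4.909), as in the other Control arrays, with 8.655 the lowest of arrays with high Xist. Lower signal over background on these arrays would raise dim and lower bright unnamed probe sets, which gives a gap above 0. The gap was -0.155 in GB replicate 2, -0.0589 in GS replicate 3 and -0.097 in Control replicate 3. The outcome stated beforehand for this explanation therefore failed. Its bound of 0 left out the spread, as the other arrays ran from -0.0931 to 0.0719, with GS replicate 3 inside that range. Each of the 3, on the other hand, had the highest receptor-gene level of its group (5.354, 5.234 and 5.231) and the lowest SD over all values (1.446, 1.472 and 1.476). Lower signal would give both, so the explanation stays open despite the failed outcome. RNA of a listed non-neuronal cell type stays open, as do dissection and RNA quality, which the labels do not record: the erythroid list came closest, at -0.0451 (SE 0.144), and in its first form, which also held the regional midbrain and hindbrain list, that list came closest at 0.0166 (SE 0.0389), equally undecided.

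For the genes called in GBS against Control, the fall of the receptor genes, which read background, was weighed as the whole cause. With their level as a covariate 42.2% of the higher and 36.1% of the lower calls still passed. This does not settle it, since their level in GBS (4.844 to 4.922) and Control (5.122 to 5.231) did not overlap. The covariate's slope therefore rests on differences within groups and may correct too little or too much. The median change of the called genes went from 0.781 to 0.44 and from -0.451 to -0.327, with median standard errors of a single gene of 0.16, 0.151, 0.114 and 0.123, so part of the changes may come from it. Sex was argued against, with a highest Xist value of 5.021 in the 6 arrays and 8.655 the lowest of arrays with high Xist. Fewer neurons as the whole cause was argued against, since it would raise the markers of all other cells alike, but the changes of 66 markers of other cell types and progenitors had an SD of 0.862, against a median standard error of a gene of 0.142, with 10 higher and 3 lower (SD 0.679 over the 30 brighter ones). That test took this form after 2 others on the lists' medians had been seen: against a bound of 0 the microglia list (-0.273, SE 0.0539) argued against it too, and against the receptor genes' median of -0.373 (SE 0.0126) it decided nothing, and a lower share of neurons as part of the cause stays open.

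Prm1 was higher in all 9 Cre-carrying arrays (7.99 to 9.66) than in the 3 Control arrays (7.18 to 7.38), by 1.51 on average. RNA of male germ cells was argued against, as 5 other late spermatid genes had a median difference of -0.117 (SE 0.0375). Protamine 1 sequence in the Cre transgene, a common source of a polyadenylation signal in transgenes, is a candidate explanation that stays open: the lowest Cre-carrying array lay 0.611 above the highest Control array, but the sequence of the construct is not in the sources used here. It cannot be told apart from a response of the gene itself, since all Control mice lack Cre.

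Arrays of 2 groups can be split 3 against 3 in 10 ways with the real one, too few for a share under 0.05. Real calls and the highest of the other splits were 2173 and 0 for GBS against Control, 3 and 0 for GS against Control, 0 and 0 for GB against Control, 720 and 0 for GBS against GS, and 1806 and 0 for GBS against GB. As many calls came from 1, 1, 10, 1 and 1 of the 10 splits. Every other split mixes arrays of both genotypes, so a real difference between them widens the spread there and calls become unlikely. The counts of 0 in the other splits are therefore no support for the real calls.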

How the results depend on the processing

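Of 177 calls of named genes 64 were kept under all alternatives and 0 turned direction. These alternatives include an adjusted p under 0.01 and at least a 2-fold change, which ended 87 and 63 of the calls by construction, so the 64 understate how many calls withstand other processing. Of 29 camera calls of gene lists 0 held with an estimated correlation. Leaving out the 3 deviating arrays and using the receptor-gene level or Xist as a covariate were chosen after seeing the data. In what follows, counts are higher and lower genes, and only counts that moved by over 1.5 times are given. For all moves below the cause was not tested, except that stricter thresholds call fewer genes by construction, and that with Xist the standard errors of all 46 interaction calls grew.

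With array weights, which ran from 0.0794 for GB replicate 2 to 10.9 for GS replicate 2, the counts were 3610 and 4127 (GBS against Control), 4203 and 4084 (GS against Control), 67 and 1 (GB against Control), 1791 and 1864 (GBS against GS), 2079 and 963 (GBS against GB) and 493 and 665 (interaction). Without the 3 deviating arrays they were 3331 and 2686, 1400 and 314, 25 and 1, 1164 and 1245, 2434 and 1007, and 120 and 293, in the same order. A fit to only the groups compared gave 3459 and 3095 for GBS against Control, 126 lower for GBS against GS, and 77 and 0 for GBS against GB, and it has no interaction value. With the receptor-gene level as a covariate the counts were 787 and 1052 for GBS against Control, 849 and 1265 for GBS against GS, 520 higher for GBS against GB, and 147 and 106 for the interaction. With Xist they were 406 lower for GBS against Control, 124 and 17 for GBS against GS, 246 and 16 for GBS against GB, and 0 and 0 for the interaction.

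Centring arrays on their medians gave 408, 140 and 256 lower genes for GBS against Control, GS and GB. Quantile normalization gave 277 lower for GBS against GB, 27 and 2 for the interaction and 1 higher for GB against Control, as did each probe set on its own. Trend and robust settings gave 3 lower for the interaction. At least 2-fold changes numbered 487 and 26, 185 and 28, and 463 and 4 for GBS against Control, GS and GB. An adjusted p under 0.01 left 591 and 61, 217 and 37, and 331 and 14 there, and 12 and 0 for the interaction.

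Leaving out each array in turn gave 631 to 3268 higher and 78 to 2865 lower genes for GBS against Control, 0 to 7 higher for GB against Control, 247 to 1100 and 45 to 580 for GBS against GS, 396 to 2199 and 25 to 1045 for GBS against GB, and 14 to 56 and 1 to 4 for the interaction. The postmitotic neuron list in GB against Control had a median of -0.421 with all arrays and of -0.625 to 0.0524 with an array left out, the last without GB replicate 2 (adjusted p = 0.706).

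Replicate numbers did not pair the arrays: residuals of the 18 same-numbered pairs correlated from -0.818 to 0.739, 7 of them above 0.1, and 4 of 12 arrays correlated best with their own number. With the replicate number as a block the counts were 993 and 190 for GBS against Control, 304 and 88 for GBS against GS, 654 and 71 for GBS against GB, and 16 higher for the interaction.

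No filter on dim genes, a filter at the 60th percentile and the mean of a gene's probe sets moved no count by over 1.5 times. Leaving out probe sets that match several transcripts by the suffix of their name was not run, since these names carry no suffix. RMA values hold no measure of signal over background per probe set, which limits what can be said of dim genes.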
